A study of Thermosynechococcus vestitus BP-1 with 39 samples.

How the data were processed

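RNA-seq was made from total RNA of Thermosynechococcus vestitus (elongatus) BP-1, a thermophilic cyanobacterium, collected by fast filtration and sequenced as single-end Illumina reads. The 39 libraries form 13 groups of 3 biological replicates. Cultures at 61 °C (heat) and at 45 °C (cold) were sampled at 0, 0.5, 3, 10 and 24 h, and control cultures at 53 °C at 3, 10 and 24 h. The labels give 61 and 45 °C for the 0 h libraries too. That these were taken before the move is assumed here, and every comparison with 0 h rests on it. No library of the control was labelled 0 or 0.5 h, and the labels give no batch. The column headers of the 3 heat libraries at 3 h carry a suffix that the labels do not explain.

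The deposited values are a signal per gene and library, in whole numbers, and were not scaled to the library. The values are coverage summed over the bases of each gene, not numbers of reads. This was read from the values: 165 of the 96564 values equalled 101, 75 equalled 202 and 60 equalled 303, against at most 20, 18 and 20 at any value within 10 of these. Coverage was therefore divided by 101 bases to give read equivalents. Per the labels, the authors trimmed reads with cutadapt; its version, the aligner, the counting tool, the genome build and the annotation are not given in the sources used here. Coverage per library summed to 23547090 to 82988527 bases (median 42646187), which is 233140 to 821669 read equivalents (median 422239).

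Locus tags were matched to the reference gene table of this strain. Of 2476 genes, 2354 matched and 643 had a symbol; the table held no product descriptions, so gene groups were built from symbols alone. Genes were kept when at least 3 libraries had 10 or more read equivalents (1010 bases), which left 2400 genes, 636 of them with a symbol, and dropped 76. Coverage was scaled per megabase of library coverage (Mb) with trimmed mean of M values (TMM) factors, with trims of 30% and 5%, and log2 transformed after adding 1. Every fold change is relative to this scaling. limma 3.58.1 in R 4.3.3 (with jsonlite 2.0.0) fitted 1 mean per group over all 39 libraries, with a mean-variance trend. Adjusted p-values are Benjamini-Hochberg values over the 2400 genes of a comparison, all tests were two-sided, and genes at an adjusted p under 0.05 were called. A test for read counts had been planned, with this limma fit as the substitute for another unit; the planned DESeq2 alternative needs read counts and was not run.

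There were 15 comparisons. Heat and cold at 3, 10 and 24 h were compared with the control of the same hour, and at 0.5 h with 0 h of the same arm. Further comparisons set the arms against each other at 0, 3, 10 and 24 h, the control at 10 and 24 h against 3 h, and the 0.5 h responses against each other. Choices were made before the data were examined unless stated otherwise. The filter in read equivalents replaced a planned filter on read counts, because the values were coverage. The list tests on log2 coverage likewise replaced planned list tests on log2 read counts. Before the data were examined, 26 gene lists were fixed; their symbols were amended after the gene table was seen and before any fit. The lists had 3 or more tested members in 21 cases. Of the other lists, RNA polymerase and sigma factors and type IV pili had 2 members each, and carbon fixation, CRISPR, and rRNA and tRNA had 0, so none of these was tested. Lists were tested in the 8 heat and cold comparisons with limma's camera on log2 coverage, at a preset correlation of 0.01 and again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance one way. List p-values were adjusted over the 168 tests.

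Named genes followed a fixed rule. Eligible were called genes with a symbol whose 3 libraries in one group all lay above or all below those of the other. Their higher group also had a mean of at least 10 read equivalents. Of these, the 3 highest and 3 lowest were named in every comparison except those of heat with cold after 0 h. To these came the 5 rising and 5 falling genes with the largest smallest change among those called the same way at all 4 times of an arm, and up to 4 members of each list that passed camera or had 3 members called at a log2 change of 1 or more. From these the text gives mainly genes whose call held without any 1 library, and says where it did not; that choice was made after the values were seen.

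The procedure was tested on simulated data with known changes of 1.5, 2 and 4 fold in 67, 67 and 65 tested genes, balanced up and down. In heat 3 h vs control 3 h it recovered 53.7% of 1.5-fold, 82.1% of 2-fold and 96.9% of 4-fold changes, and 5.52% of its calls were false. In heat 0.5 h vs heat 0 h it recovered 56.7%, 82.1% and 100% of them, with 3.66% false calls. It called the 1 list given a change and 0 of 20 random lists. Simulated genes were independent and had the same spread (squared coefficient of variation 0.00745). Far fewer genes changed than were called in the real heat comparisons, so these shares of false calls need not hold there. Among 39 pairs of replicates, Pearson's r of log2 coverage across genes was 0.951 to 0.987, and squared differences were 1.35 to 7.90 times those of counting error. Alternatives were a minimum log2 fold change of 1, a pseudocount of 0.1, relative log expression (RLE) factors, library totals alone, no filter, a fit of only the compared libraries, the replicate number as a block over all libraries or within an arm, 0 h of the same arm as comparator (at 0.5 h, the 6 libraries of both arms at 0 h), and leaving out each library. Added after seeing the data were limma-voom weights, the 3 and 10 h controls together or the 10 h control alone as comparator at 24 h, and the 0 h comparator for the lists.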

Results

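Transcript coverage was measured in 39 libraries of Thermosynechococcus vestitus BP-1, a cyanobacterium of hot springs, kept at 53 °C or moved to 61 °C (heat) or 45 °C (cold). Each of the 13 groups of temperature and time had 3 biological replicates, so n = 3 for every group mean. Libraries held 233140 to 821669 read equivalents, and levels are coverage per megabase of scaled library coverage (per Mb). The 10 genes with most coverage took 23.2 to 32.9% of a library. The first principal component carried 44.5% of the variance and the second 8.28%. On the first, the mean score was 26.9 at 0.5 h of heat and 18.3 at 24 h, against -21.9 and -16.7 in cold. The control lay at -7.58 at 3 h, -6.33 at 10 h and 7.99 at 24 h, where it stood nearer the heat groups.

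**Figure D1:**
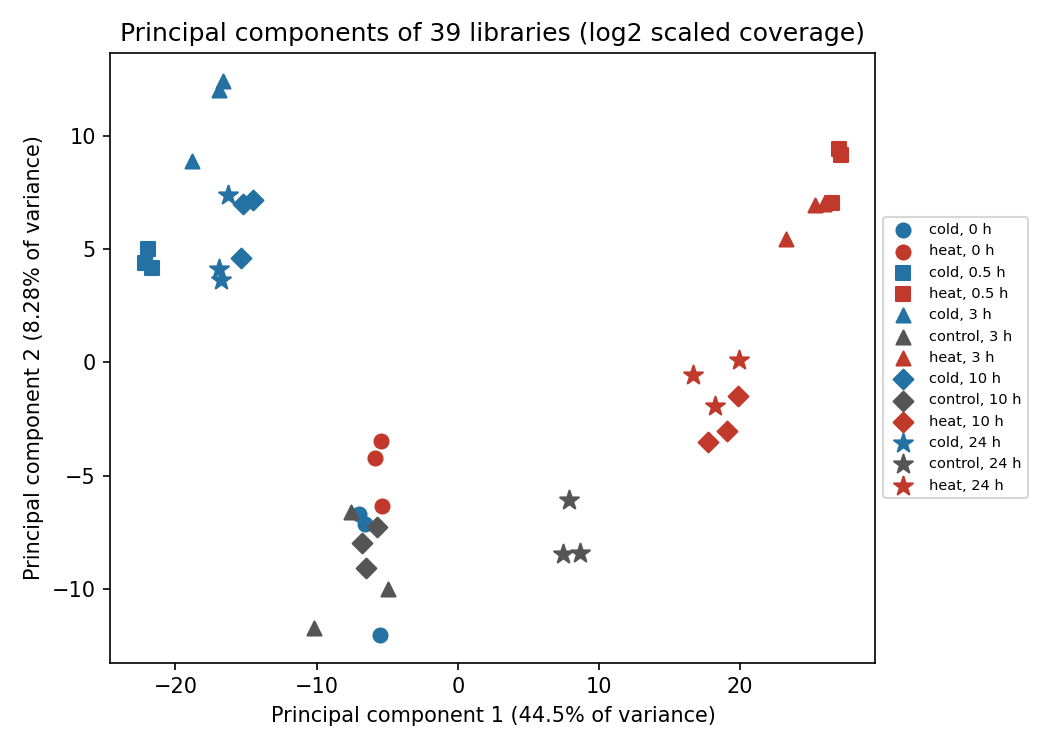
Scores of the 39 libraries on the first and second principal components of log2 scaled coverage, which carry 44.5% and 8.28% of the variance; each point is 1 library and colours and symbols mark the group. From 0.5 h on, heat libraries lie at the positive end of the first component, with group means of 18.3 to 26.9, and cold libraries at the negative end, while 0 h libraries lie beside the 3 and 10 h controls.

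After 0.5 h at 61 °C, transcripts of groES and groL tll0185, for the GroE chaperonin, which folds other proteins, rose most among genes with a symbol. Some of those for uptake and assimilation of nitrogen were among the genes that fell most. A second groL gene, tlr1412, overlapped its level at 0 h, with log2 coverage of 9.514 to 9.919 against 9.485 to 9.659. Coverage of groES (tll0186) rose from 542 ± 49.3 to 8580 ± 683 per Mb (SD, n = 3), a log2 fold change of 3.98 (SE 0.15, limma adjusted p = 2.7e-25). That of its partner groL (tll0185) rose from 5110 ± 365 to 62000 ± 8490, a log2 fold change of 3.60 (SE 0.12). Coverage of urtA (tlr1120), the binding protein of the urea transporter, fell from 904 ± 98.4 to 24.1 ± 4.3, a log2 fold change of -5.18 (SE 0.18, adjusted p = 8.8e-27). The glutamine synthetase gene glnA (tll1588) had a log2 fold change of -2.78 (SE 0.14), and ntrB (tlr1351) one of -3.19 (SE 0.23).

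Several lists were called at 0.5 h of heat. Lists were built from symbols and can hold part of a complex or pathway, so each count here and below refers to list members only. The photosystem I list held psaA, psaB, psaC, psaJ, psaK, psaM and psaX, and the nitrogen assimilation list did not hold ntrB. Among 13 chaperone genes 10 rose and 0 fell, and adjusted over the list alone the counts were the same, 10 and 0 (camera adjusted p = 9.47e-05; adjusted p = 0.0436 with an estimated correlation). All 10 protease genes rose, also adjusted over the list alone (adjusted p = 0.000307; adjusted p = 0.0215 with an estimated correlation); clpS (tll0211), whose product selects substrates for the Clp protease, had a log2 fold change of 1.39 (SE 0.17) and clpX (tlr0510) one of 0.98 (SE 0.14). All 7 photosystem I genes fell, also adjusted over the list alone (adjusted p = 7.31e-05; adjusted p = 0.016 with an estimated correlation), psaK (tsr2273) by 2.62 (SE 0.18) and the reaction centre genes psaA (tlr0731) and psaB (tlr0732) by 1.21 (SE 0.16) and by 1.12 (SE 0.17) on the log2 scale. All 6 ATP synthase genes fell, also adjusted over the list alone (adjusted p = 0.000265; adjusted p = 0.0436 with an estimated correlation), with log2 fold changes of -1.11 for atpE (tlr0431, SE 0.12) and -0.97 for atpA (tlr0435, SE 0.09). Of 50 ribosomal protein genes 33 rose and 1 fell, or 34 and 2 adjusted over the list alone (adjusted p = 0.000106; adjusted p = 0.0809 with an estimated correlation). Of 10 nitrogen assimilation genes 5 fell and 1 rose, the same counts adjusted over the list alone (adjusted p = 0.011; adjusted p = 0.0809 with an estimated correlation). The phycobilisome list held genes of the light-harvesting antenna (apcA, apcB, apcD and cpcA) and also nblB. Of its 6 genes 5 fell, also adjusted over the list alone (camera adjusted p = 0.0237, or 0.456 with an estimated correlation). Among them apcA (tll0957) had a log2 fold change of -1.15 (SE 0.13). Without replicate 1 of heat 0 h the phycobilisome call was lost (adjusted p = 0.0517). In all, 1162 of 2400 genes were called, 612 up and 550 down.

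At 3 h of heat, measured against the 53 °C control of the same hour, groES and groL tll0185 stood lower than at 0.5 h but still above the control. urtA remained far below the control. groL tll0185 was at 9940 ± 748 against 4200 ± 322 per Mb (log2 fold change 1.24, SE 0.12), and groES had a log2 fold change of 1.03 (SE 0.15). The second groL gene, tlr1412, lay below the control, with log2 coverage of 8.976 to 9.216 against 9.462 to 9.591. Among 13 chaperone genes 6 rose and 3 fell, and the list was not called (camera adjusted p = 0.225). clpS tll0211 had the highest value among well covered genes with a symbol, 2.39 (SE 0.17, limma adjusted p = 3.2e-16). The second clpS gene, tsr1087, was called up at 0.5 h of heat but not at 3, 10 or 24 h. urtA had -4.20 (SE 0.18), urtC (tlr1122), a permease gene of the same transporter, -2.43 (SE 0.20), ntrB -3.00 (SE 0.23) and glnA -2.36 (SE 0.14). psaA and psaB fell by 1.12 (SE 0.16) and by 1.39 (SE 0.17) on the log2 scale. rpsF (tlr1279) and rpmA (tsl0166), ribosomal protein genes, rose by 1.51 (SE 0.20) and 1.41 (SE 0.13), or by 0.999 and 0.743 against heat 0 h, and acsF (tlr1722), a gene of chlorophyll synthesis, by 1.60 (SE 0.19).

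In heat 3 h vs control 3 h, limma called 1133 genes, 552 up and 581 down; with library totals alone the split was 806 up and 409 down, and the median of all genes moved from 0 to 0.19. Of 50 ribosomal protein genes 22 rose and 6 fell, or 23 and 6 adjusted over the list alone (camera adjusted p = 0.0137; adjusted p = 0.368 with an estimated correlation). Of 7 photosystem I genes 6 fell, also adjusted over the list alone (adjusted p = 0.0389; adjusted p = 0.203 with an estimated correlation); the photosystem I call was lost without replicate 2 of control 3 h (adjusted p = 0.0666) or of heat 3 h (adjusted p = 0.0596). Of 10 nitrogen assimilation genes 6 fell and 3 rose, the same adjusted over the list alone (adjusted p = 0.047; adjusted p = 0.203 with an estimated correlation). The nitrogen assimilation call was lost without replicate 3 of heat 3 h (0.0735) or replicates 2 (0.059) or 3 (0.0608) of control 3 h. It was also lost without cold 0 h replicate 2 (0.0524) or 3 (0.0529), heat 0 h replicate 1 (0.0517), cold 0.5 h replicate 1 (0.0518) or 2 (0.0502), cold 3 h replicate 2 (0.0503) or cold 24 h replicate 1 (0.0502), through the shared fit. The transposase gene tnpA (tll2031) had the highest log2 fold change, 3.21 (SE 0.58), but it is 1 of 7 genes of this symbol at 9.83 to 11.4 read equivalents per library, and tll2031 was not called against heat 0 h (1.36), and which copy the reads came from is uncertain.

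By 10 h of heat groES, groL tll0185, clpS tll0211 and urea transporter genes still differed from the control, while psaA and psaB were no longer called. groL tll0185 had a log2 fold change of 1.37 (SE 0.12) and groES of 1.30 (SE 0.15). Coverage of groL tll0185 was 7920 ± 1490 against 3060 ± 552 per Mb (n = 3), and its value against heat 0 h was 0.62. For groL tlr1412 the groups overlapped, with log2 coverage of 9.139 to 9.261 against 9.223 to 9.459. clpS tll0211 stood at 2.12 (SE 0.17, limma adjusted p = 3.7e-14). ntrB was at -2.49 (SE 0.23), urtA at -1.39 (SE 0.18) and urtE (tlr1124), an ATPase gene of the urea transporter, at -1.57 (SE 0.36; -1.01 against heat 0 h). The reverse transcriptase gene ltrA (tll0114) of a group II intron, a mobile element, fell by 2.34 (SE 0.15) on the log2 scale, from 54100 ± 8050 to 10600 ± 1330; how reads were divided among the 6 genes of this symbol was not tested. All ATP synthase genes but 1 fell, 5 of 6, also adjusted over the list alone (camera adjusted p = 0.000342; adjusted p = 0.0436 with an estimated correlation), atpA by 1.01 (SE 0.09).

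Among chaperones 5 of 13 rose at 10 h, or 6 adjusted over the list alone (adjusted p = 0.0325; adjusted p = 0.368 with an estimated correlation). The chaperones call was lost without replicate 3 of heat 10 h (0.0826) and against 0 h of the same arm (0.226). In heat 10 h vs control 10 h, 811 genes were called, 374 up and 437 down, and 597 up and 286 down with library totals alone, where the median of all genes was 0.17.

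At 24 h of heat fewer genes differed from the control, 246 in all, 72 up and 174 down. groL tll0185 was still higher (log2 fold change 0.64, SE 0.12, limma adjusted p = 0.00023), as was clpS tll0211 (0.75, SE 0.17). The methionine synthase gene metE (tlr1090) was also higher (0.99, SE 0.21). Its coverage was 168 ± 16.8 against 83.5 ± 2.51 per Mb (n = 3). urtA was lower (-0.70, SE 0.18), as were psaK (-0.89, SE 0.18) and ltrA tll0114 (-1.49, SE 0.15). Of 6 phycobilisome genes 2 fell, apcA by 0.58 (SE 0.13) and apcB (tll0956) by 0.52 (SE 0.12), or 5 adjusted over the list alone (camera adjusted p = 0.00952; adjusted p = 0.384 with an estimated correlation). Against the 3 and 10 h controls the values were larger, 1.24 for groL (tll0185), 2.14 for clpS (tll0211), -1.05 for urtA (tlr1120), -2.51 for ltrA (tll0114), -1.10 for apcA (tll0957) and -1.18 for apcB (tll0956). Against heat 0 h they were 1.52 for clpS, -1.33 for urtA, -0.895 for apcA and -1.19 for apcB. The phycobilisome call was lost without replicate 1 of control 24 h (0.0705) and against 0 h of the same arm (0.166). In heat 24 h vs control 24 h the count was 110 without replicate 3 of heat 24 h and 97 in a fit of only these libraries, but 819 against heat 0 h and 1111 against the 3 and 10 h controls together, an alternative chosen after seeing the data. With library totals alone 120 genes were up and 123 down.

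Across the 4 heat times 31 genes were called up each time and 128 down each time, out of 1713 called at any time. The counts were 47 up and 96 down with library totals alone, and 173 up and 239 down with 0 h as comparator (both arms at 0 h for the first time). That comparator leaves out the 24 h control, which had changed, but also the other controls. It reuses the same 0 h libraries at each later time, which can raise the agreement between times. Those with the largest sustained rise included tlr1001 (log2 fold changes of 2.76, 2.32, 2.42 and 1.63 at 0.5, 3, 10 and 24 h, SE 0.14), tlr0313 (2.78, 1.30, 1.28 and 0.82, SE 0.15) and ispD (tlr0605, a gene of isoprenoid synthesis; 2.06, 0.96, 1.24 and 1.19, SE 0.28). The sustained falls included tlr0319 (-2.20, -3.37, -2.47 and -1.36, SE 0.14) and tlr0317 (-2.23, -2.57, -2.01 and -1.36, SE 0.12). None of tlr1001, tlr0313, tlr0317 and tlr0319 has a symbol in the gene table.

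**Figure D2:**
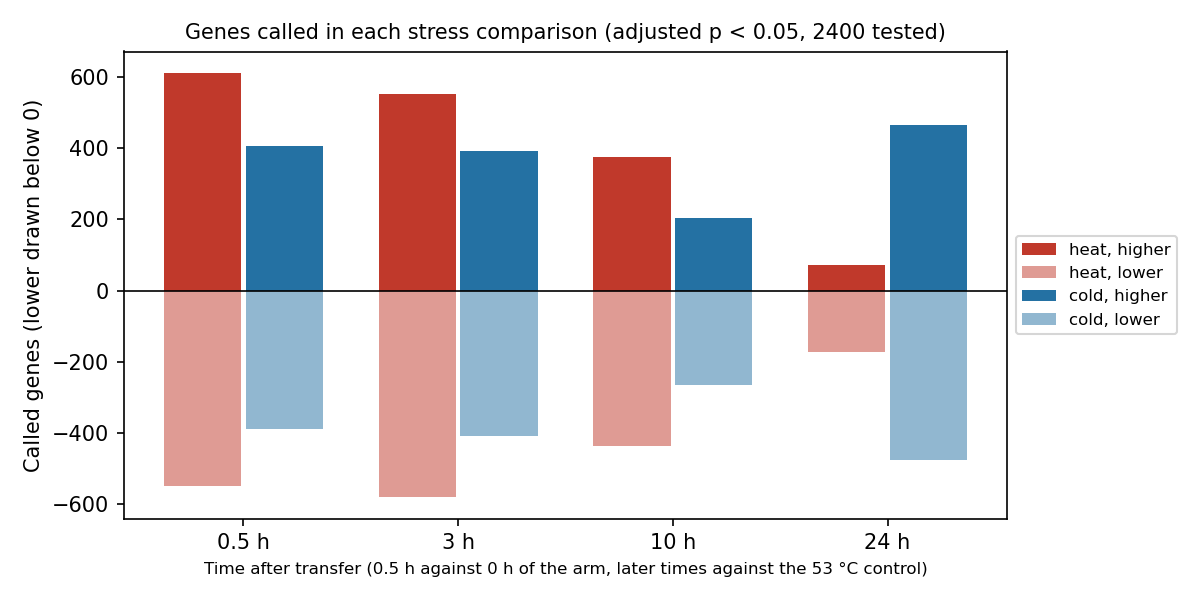
Number of genes called by limma at an adjusted p under 0.05 in each of the 8 heat and cold comparisons, with genes up above 0 and genes down below it. Heat falls from 1162 genes at 0.5 h to 246 at 24 h, and cold runs from 469 at 10 h to 942 at 24 h; the 24 h control itself had changed, and against the 10 h control heat 24 h had 857 called genes and cold 24 h 480.

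After 0.5 h at 45 °C, the GroE genes fell and ribosomal protein genes rose. groL (tll0185) fell from 5630 ± 450 to 1300 ± 89.5 per Mb (SD, n = 3), a log2 fold change of -2.11 (SE 0.12, limma adjusted p = 8.3e-18), and groES from 714 ± 58.9 to 177 ± 38.4 (-2.03, SE 0.15). The second groL gene, tlr1412, rose by 0.68 (SE 0.10). The ribosomal protein genes rplJ (tlr0297), rpsS (tsr0085) and rplE (tlr0093) rose by 1.58 (SE 0.20), 1.49 (SE 0.16) and 1.27 (SE 0.13) on the log2 scale, and prfB (tll0527), a peptide chain release factor gene, fell by 1.60 (SE 0.23).

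Of 50 ribosomal protein genes 38 rose and 1 fell at 0.5 h of cold, or 41 and 3 adjusted over the list alone (camera adjusted p = 2.21e-13; adjusted p = 0.0042 with an estimated correlation). Of 6 ATP synthase genes 3 rose, also adjusted over the list alone (adjusted p = 0.0137; adjusted p = 0.201 with an estimated correlation), atpE by 1.06 (SE 0.12) and atpA by 0.61 (SE 0.09). Of 6 phycobilisome genes 3 fell, or 4 adjusted over the list alone (adjusted p = 0.0467; adjusted p = 0.494 with an estimated correlation). The phycobilisome call was lost without cold 0 h replicate 2 (0.0826) or 3 (0.0648), cold 0.5 h replicate 1 (0.0812) or 3 (0.0529), or control 3 h replicate 1 (0.0504) or 2 (0.0537), and against the 6 libraries of both arms at 0 h (0.227). psaK fell by 1.55 (SE 0.18). limma called 795 genes, 405 up and 390 down.

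At 3 h of cold, ribosomal protein and ATP synthase genes were above the control of the same hour. rplL (tlr0298) was at 881 ± 149 against 286 ± 17.9 per Mb (log2 fold change 1.61, SE 0.14, adjusted p = 4.7e-12), rplJ rose by 1.30 (SE 0.20) and rpmI (tsl2159) by 1.22 (SE 0.12). ndhM (tll0447), a subunit gene of the NDH-1 complex of cyclic electron flow, had the highest value among genes that met the naming rule, 1.88 (SE 0.19), or 0.664 against cold 0 h. psaK fell by 2.50 (SE 0.18), urtA by 1.36 (SE 0.18), urtC by 1.45 (SE 0.20) and groL tll0185 by 1.28 (SE 0.12), while groL tlr1412 rose by 1.13 (SE 0.10; 0.738 against cold 0 h).

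Of 50 ribosomal protein genes 31 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 1.67e-10; adjusted p = 0.0108 with an estimated correlation), and all 6 ATP synthase genes rose, also adjusted over the list alone (adjusted p = 0.000307; adjusted p = 0.0436 with an estimated correlation). Of 25 photosystem II genes 10 fell and 2 rose, or 11 and 3 adjusted over the list alone (adjusted p = 0.0208; adjusted p = 0.304 with an estimated correlation). Among them, psbD (tlr0455) and psbA (tlr1843), for the reaction centre proteins D2 and D1, fell by 1.24 (SE 0.13) and by 0.83 (SE 0.13); psbA tlr1843 had -0.53 against cold 0 h. Whether other genes of these symbols share their reads was not tested. The photosystem II call was lost without replicate 2 of control 3 h (0.0537) and against 0 h of the same arm (0.311). In cold 3 h vs control 3 h, 801 genes were called, 391 up and 410 down, and 570 up and 271 down with library totals alone, where the median of all genes was 0.14.

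At 10 h of cold, copies of psbD and psbA and genes of urea uptake and proteolysis were below the control. psbD tlr0455 was at 3160 ± 336 against 7600 ± 965 per Mb (log2 fold change -1.26, SE 0.13, adjusted p = 5.2e-10), with the other copy, tlr1630, at -1.20 (SE 0.13), and psbA tlr1843 at -1.11 (SE 0.13). The photosystem II list, with 8 of 25 genes down and 2 up, the same adjusted over the list alone, was not called (camera adjusted p = 0.0695). urtA fell by 1.19 (SE 0.18) and urtC (tlr1122) by 1.13 (SE 0.20; -0.622 against cold 0 h). The membrane protease genes ftsH3 (tll0131) and ftsH4 (tlr0528) fell by 0.81 (SE 0.10) and by 0.62 (SE 0.13; -0.405 for ftsH4 against cold 0 h). The NDH-1 genes ndhM and ndhN (tlr1130) had log2 fold changes of 1.35 (SE 0.19) and 1.16 (SE 0.23), but were not called against cold 0 h (0.32 and 0.37).

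Of 10 proteases 5 fell at 10 h of cold, also adjusted over the list alone (camera adjusted p = 0.00326; adjusted p = 0.0436 with an estimated correlation). Of 6 ATP synthase genes 3 rose, also adjusted over the list alone (adjusted p = 0.00326; adjusted p = 0.0887 with an estimated correlation). Of 10 nitrogen assimilation genes 4 fell, or 5 adjusted over the list alone (adjusted p = 0.00503; adjusted p = 0.0516 with an estimated correlation). Of 26 genes in the list amino acyl tRNA synthetases and elongation 8 rose, also adjusted over the list alone (adjusted p = 0.0137; adjusted p = 0.384 with an estimated correlation), and that call was lost without replicate 3 of control 10 h (0.0621). Against 0 h of the same arm the calls of proteases (0.159), ATP synthase (0.696) and amino acyl tRNA synthetases and elongation (0.441) were lost. In cold 10 h vs control 10 h, 469 genes were called, 203 up and 266 down, and 455 up and 143 down with library totals alone, where the median of all genes was 0.19.

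At 24 h of cold, hpnH (tll0596), a gene of hopanoid lipid synthesis, was at 528 ± 44.2 against 129 ± 38.1 per Mb (n = 3), a log2 fold change of 2.06 (SE 0.15, adjusted p = 1e-14). The control itself had changed in hpnH from 3 to 24 h by -1.13 (SE 0.15), and the cold value was 1.00 against the 3 and 10 h controls and 0.461 against cold 0 h. atpE, atpA and atpB (tlr0430) rose by 1.23 (SE 0.12), 1.07 (SE 0.09) and 0.91 (SE 0.10), or by 0.731, 0.502 and 0.536 against the 3 and 10 h controls; atpA (tlr0435) and atpE (tlr0431) kept their calls against cold 0 h, atpA at 0.534. groL tlr1412 rose by 1.06 (SE 0.10; 0.305 against cold 0 h), while groL tll0185 fell by 0.93 (SE 0.12; -0.336 against the 3 and 10 h controls). psbA tlr1843 and its copy tlr1477 fell by 0.94 (SE 0.13) and by 1.46 (SE 0.16), and psaK by 1.36 (SE 0.18). The phospholipid synthesis gene pgsA (tll1275) had a log2 fold change of 2.01 (SE 0.67) at 21.7 ± 3.21 against 5.74 ± 4.92 per Mb, and was not called without replicate 2 of control 24 h (1.51), with a pseudocount of 0.1 (2.26) or against cold 0 h (1.52).

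Of 6 ATP synthase genes 5 rose at 24 h of cold, or 6 adjusted over the list alone (camera adjusted p = 1.05e-05; adjusted p = 0.016 with an estimated correlation). Of 10 proteases 8 fell, or 9 adjusted over the list alone (adjusted p = 0.00443; adjusted p = 0.0516 with an estimated correlation). Against 0 h of the same arm neither ATP synthase (0.179) nor proteases (0.253) was called, and atpB (tlr0430) had a log2 fold change of 0.22 there. In cold 24 h vs control 24 h limma called 942 genes, 465 up and 477 down; the count was 658 against the 3 and 10 h controls, 643 against cold 0 h and 480 against the 10 h control.

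Across the 4 cold times 62 genes were called up each time and 79 down each time, out of 1565 called at any time, or 125 up and 47 down with library totals alone and 124 up and 118 down with 0 h as comparator. Sustained rises included tll1655 (log2 fold changes of 1.38, 1.54, 1.53 and 2.25 at 0.5, 3, 10 and 24 h, SE 0.22), tll1545 (1.80, 1.10, 0.94 and 2.24, SE 0.20) and hemC (tll1646, a gene of tetrapyrrole synthesis; 1.15, 0.94, 1.02 and 1.29, SE 0.23). Sustained falls included psaK, tlr0548 (-1.06, -2.04, -1.75 and -1.64, SE 0.17) and tsr0549 (-0.96, -2.55, -1.56 and -1.37, SE 0.20). The other 12 lists had 0 camera calls in the 168 tests, with a lowest adjusted p of 0.0702 (mobile elements at 0.5 h of cold). They were cytochrome b6f and carriers, NDH-1, cold RNA chaperones and ribosome assembly, fatty acid synthesis, oxidative stress, high light, tetrapyrrole synthesis, circadian clock, iron, glycogen, mobile elements and regulators of the two-component kind. The cold list held only rbfA, nusA, era, der, infA and infB, and the high light list only crtE, crtD, crtR and crtG. Both were narrower than their names. So were the oxidative stress list, with only trxA, bcp and trxB genes, and the two-component list, with only rpaB, nblR and nblS. The absence of a call in such lists says little about the processes they are named for. Camera asks for a net shift one way, and members of some lists moved both ways. At 0.5 h of heat 9 of 15 mobile element genes rose and 5 fell. Of 18 tetrapyrrole genes 7 rose and 8 fell, where 48.4% of all genes were called. The mobile element list held only tnpA and ltrA genes, whose copies may share reads, so its counts may stand for fewer elements. Of the 25 camera calls 10 held with an estimated correlation and 25 by fry, which made 90 calls.

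**Figure D3:**
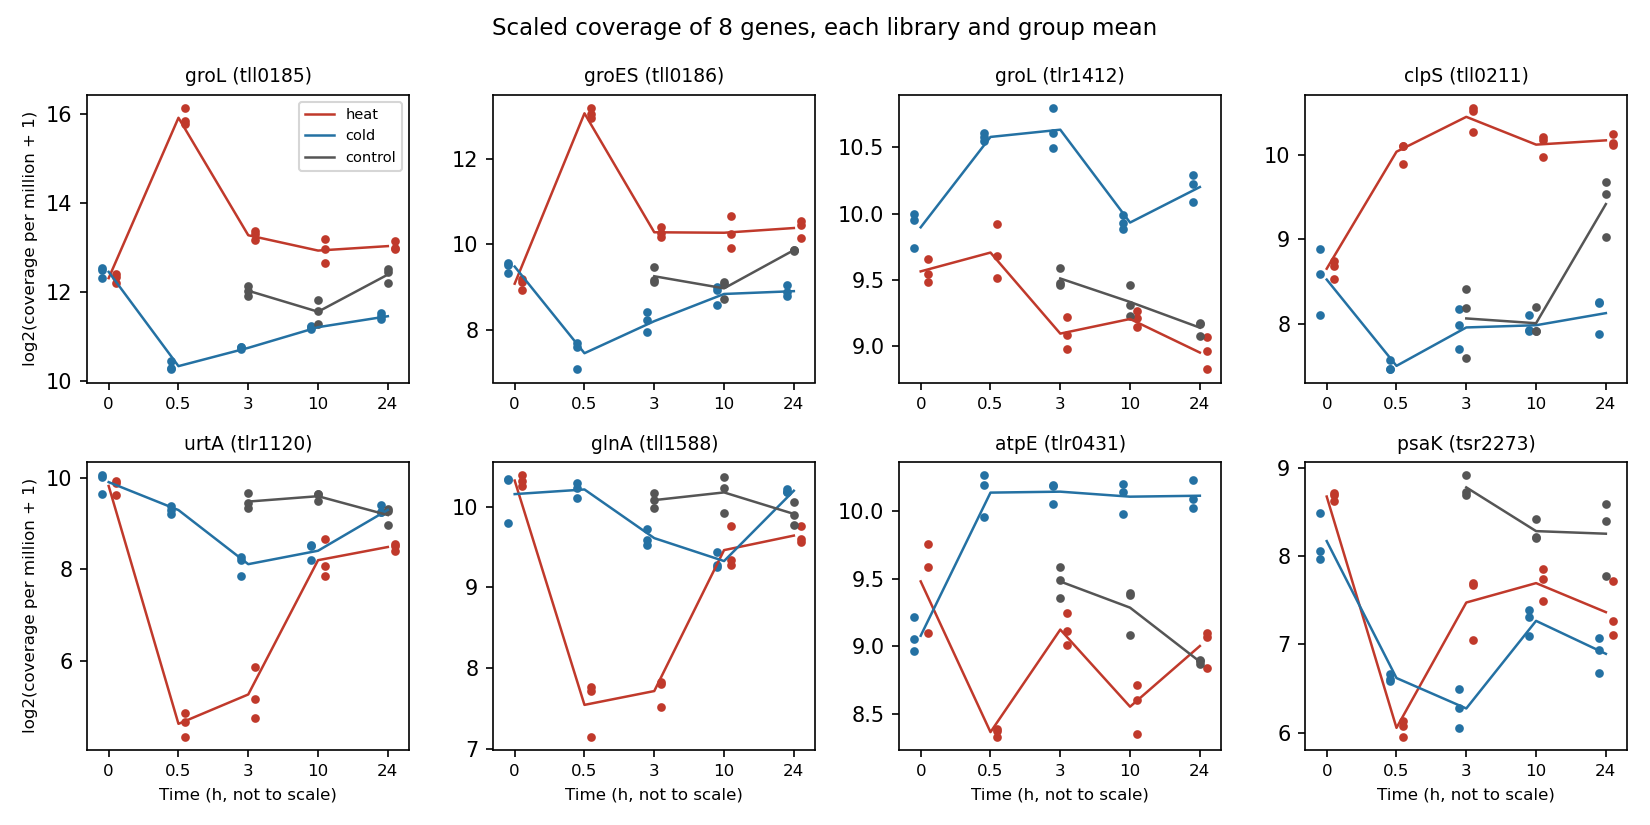
Scaled coverage (log2 of coverage per Mb plus 1) of 8 genes over time (h) at 45, 53 and 61 °C; each point is 1 library and lines join the group means (n = 3). groES rises by 3.98 at 0.5 h of heat and urtA falls by 5.18 on the log2 scale.

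**Figure D4:**
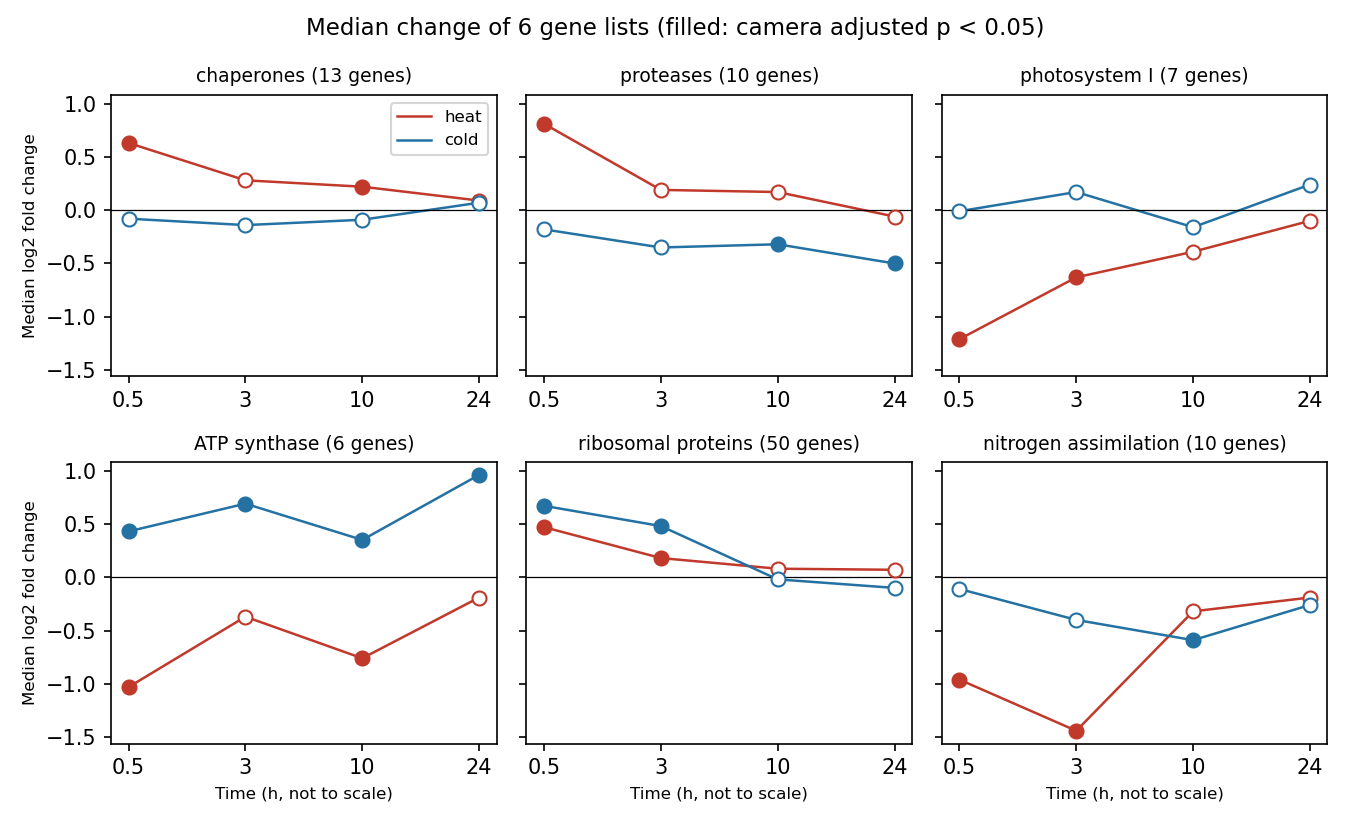
Median log2 fold change of the members of 6 gene lists over time (h) in heat and cold, with filled points where camera gave a call. Photosystem I has a median of -1.21 and ATP synthase of -1.03 at 0.5 h of heat, against 0.43 for ATP synthase at 0.5 h of cold.

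Set directly against each other at 0.5 h, heat and cold differed most, among genes with a symbol, in groES, groL tll0185, ntrB and urtA. The difference of the 0.5 h responses was 6.01 for groES (SE 0.22, limma adjusted p = 5.5e-26), 5.71 for groL tll0185 (SE 0.17), -4.67 for ntrB (SE 0.33), -4.57 for urtA (SE 0.26) and -2.17 for atpE (SE 0.18). At 3 h, heat against cold gave 2.52 for groL tll0185 (SE 0.12) and 2.49 for clpS tll0211 (SE 0.17). It gave -2.84 for urtA (SE 0.18), -1.54 for groL tlr1412 (SE 0.10) and -1.24 for atpA (SE 0.09). At 10 h urtA no longer differed detectably (-0.21, SE 0.18, adjusted p = 0.36), while atpE did (-1.55, SE 0.12). At 24 h clpS tll0211 differed by 2.05 (SE 0.17) and acsF by 2.02 (SE 0.19). The genes called numbered 1182 for the 0.5 h responses (579 higher and 603 lower in heat), 1330 at 3 h (677 and 653), 1179 at 10 h (578 and 601) and 1170 at 24 h (592 and 578).

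Across genes, which are not independent replicates, the heat and cold changes at 0.5 h, which share no library, had a Pearson r of -0.305 and a Spearman rho of -0.309. Of the genes called in both, 60 rose and 59 fell in both, while 196 rose in heat and fell in cold and 169 did the reverse. Independent lists would give 103, 89.4, 99.4 and 92.8. At 3 h r was 0.113, with 118 genes up and 125 down in both (89.9 and 99.3 if independent), but both arms were compared with the same control libraries. Unchanged groups simulated with a shared control gave an r of 0.498, which the sharing alone produces when nothing changes, so it cannot be set against 0.113. The covariance was 0.0508, against 0.0321 simulated, and in the simulation 0 genes were called up and 0 down in both. The simulation drew noise independently for each gene, with a spread pooled over all groups. The 3 h controls spread most on the first principal component (SD 2.62, against 0.231 to 1.65 in other groups). The simulated values may therefore understate what the sharing gives at 3 h. With 0 h of each arm as comparator r was -0.116 at 3 h, so the sign turned. At 10 h r was -0.00681 and at 24 h -0.155, against -0.0902 and -0.0944 with 0 h. Unchanged groups simulated with a shared control gave an r of 0.501 at both times. The covariances were -0.0019 and -0.0388, against 0.0321 and 0.0322 simulated. At 24 h, 102 genes fell in heat and rose in cold (33.7 if independent), 29 did the reverse (14.3), and 10 rose and 12 fell in both (14 and 34.6).

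The starting cultures and the control were compared to show change without a shift in temperature. At 0 h, secE (tsr0293), a protein translocase gene, was higher in the heat arm by 0.87 (SE 0.16, adjusted p = 0.00077), at 342 ± 12.5 against 188 ± 32 per Mb (n = 3), and ndhI (tlr0668), an NDH-1 gene, was lower by a log2 fold change of -0.84 (SE 0.16). In heat 0 h vs cold 0 h limma called 143 genes, 71 higher and 72 lower in the heat arm, and 94 in a fit of only these libraries. Without cold 0 h replicates 1, 2 or 3 the count was 32, 77 or 95, and without heat 0 h replicates 1, 2 or 3 it was 92, 41 or 20.

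Between 3 and 10 h the control changed in 5 genes, 1 up and 4 down, named here after their values were seen. They were tll0478 (2.64, SE 0.59), tll0365 (-0.47, SE 0.11), tll1715 (-0.80, SE 0.19), tll1724 (-0.49, SE 0.10) and tlr0906 (-0.90, SE 0.21), and none has a symbol. In control 10 h vs control 3 h, 266 genes had an unadjusted p under 0.05, and the count was 0 with library totals alone, where the median of all genes was 0.11, and 1 with limma-voom. Without control 3 h replicates 1, 2 or 3 the count was 0, 21 or 19, and without control 10 h replicates 1, 2 or 3 it was 2, 2 or 0.

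Between 3 and 24 h the control changed more. psbN (tsr1387) rose from 87.5 ± 33.4 to 235 ± 21.4 per Mb (n = 3, limma adjusted p = 6e-07). On the log2 scale clpS tll0211 rose by 1.35 (SE 0.17) and rlmD (tlr0942), an RNA methyltransferase gene, by 2.09 (SE 0.45). ilvC (tll2254), a gene of branched-chain amino acid synthesis, fell by 1.44 (SE 0.16) and bchB (tll2392), of chlorophyll synthesis, by 1.44 (SE 0.29) on the log2 scale; without replicate 1 of control 3 h the value of bchB was -0.912. In control 24 h vs control 3 h, 266 genes were called up and 285 down, and 488 up and 146 down with library totals alone, where the median of all genes was 0.15. The count was 220 in a fit of only these libraries and 325 without replicate 1 of control 3 h.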

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

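All tests on the 24 h control and on ltrA, and the values against cold 0 h of genes whose sign changed, were chosen after those results were seen; the tests on urt and glnA were stated first, and the bounds of the tests on exchanged labels, on warming and on scaling of urt and glnA were changed after these had been run.

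The control at 24 h lay nearer the heat libraries than the control at 3 or 10 h did. Labels exchanged with another group stay open: the fewest genes called against any other group were 246, for heat 24 h, but an exchange need leave no group equal to it, and 2 groups, heat 0 h and cold 0 h, lay nearer the 10 h control (186 and 241 genes called) than the 24 h control did (369). Scaling did not remove the change from 3 h, with 554 genes called under RLE factors and 634 under library totals. Culture age alone, acting alike at any temperature, was set to move the same genes at 45 °C, where only 47.9% of them moved the same way. But the change at 45 °C from 3 to 24 h, with 224 genes called, also holds the course of the cold response. The share therefore cannot exclude an effect of age at 53 °C. Warming of the control cultures cannot be told from a change of growth state at 53 °C: of 8 chaperone and protease genes that rose in early heat, 4 (50%) rose, clpS by 1.35 (SE 0.17), and groL (0.36, SE 0.12) and groES (0.61, SE 0.15) by 0.265 and 0.47 of their change at 10 h of heat, less than the 0.5 that warming was set to need, but clpB by 1.3 of it.

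Of urtA, urtC, urtD, urtE and glnA, 3 were called below the control in both stresses at 3 h and 4 at 10 h; urtD was not called in cold at either time, nor urtE in cold at 3 h. Control libraries that were high by accident would leave these genes unchanged against 0 h. But at 3 h of cold their median log2 fold change against 0 h of the same arm was -0.55, with urtA, urtC and glnA called. At 10 h of cold the median was -0.64 with the same genes called, but urtE was not (-0.64, SE 0.36, limma adjusted p = 0.19). Scaling of the libraries stays open as part of the pattern: under library totals 2 of the 5 genes were called in both stresses at 3 h and 3 at 10 h, and the bounds set for and against scaling were both met at 3 h. The lost calls were glnA at 3 h of cold, from -0.47 (SE 0.14) to -0.32 (SE 0.14), and urtE at 10 h of cold, from -1.12 (SE 0.36) to -0.94 (SE 0.37), while at 3 h of cold urtA kept -1.21 (SE 0.18) and urtC -1.30 (SE 0.20).

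Of 6 ltrA genes, 5 fell at 4 heat times, while tlr0620 did not: it rose at 0.5 h (0.636, SE 0.128) and 24 h (0.611). Over tlr0031, tlr0308, tlr0522 and tlr1161 the spread of the log2 fold changes was at most 0.713 of their standard error, which reads shared between near-identical copies would give, so the change may belong to 1 of these; a common regulation of the 4 genes was not tested and stays open. The copy tll0114 had 19070 read equivalents per library on average, against 2079 for tlr0620.

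The responses at 0.5 h differed between heat and cold in 1182 genes. Among 100 splits of the libraries, 1 had as many, the real one, and the highest other had 1157. The 8 other splits that left the 0.5 h libraries in their groups and exchanged only 0 h libraries gave 1102 to 1157 genes, and the 91 that mixed the 0.5 h libraries 0 to 1, so the count rests on the 0.5 h libraries, and the share by itself says little about chance. Lists differed in 4 cases. Proteases were higher in heat and ATP synthase lower, each also with an estimated correlation (adjusted p = 0.035 for both). Chaperones were higher and photosystem I lower, but lost the call with an estimated correlation (adjusted p = 0.11 for both).

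The heat effect at 10 h differed from that at 3 h in 73 genes (47 higher, 26 lower) and in 3 lists. Of these, nitrogen assimilation, upward, held with an estimated correlation (adjusted p = 0.02), and ATP synthase (0.17) and ribosomal proteins (0.45), downward, did not. The heat effect at 24 h differed from that at 3 h in 411 genes (226 higher, 185 lower), with 326 called between these times within the heat arm, and in 2 lists, nitrogen assimilation upward and ribosomal proteins downward, both lost with an estimated correlation (adjusted p = 0.18 and 0.52). The cold effect at 10 h differed from that at 3 h in 79 genes (29 higher, 50 lower) and in 1 list, ribosomal proteins (adjusted p = 2.8e-17, and 0.00049 with an estimated correlation). The cold effect at 24 h differed from that at 3 h in 448 genes (235 higher, 213 lower), with 224 called between these times within the cold arm, and in 1 list, again ribosomal proteins (adjusted p = 6.7e-12, and 0.0036 with an estimated correlation). Both 24 h differences include the change of the control from 3 to 24 h, 266 genes up and 285 down.

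Several cold effects, measured against the control of the same hour, had another sign after 3 h than at 3 h. The ribosomal protein gene rplD (tlr0082) went from 0.47 at 3 h to -0.43 at 10 h and -0.90 at 24 h (SE 0.12), and turned also against cold 0 h (0.41, -0.66 and -0.82). The gene rplE (tlr0093) went from 0.59 to -0.49 and -0.37 (SE 0.13), and rpsS (tsr0085) from 0.83 to -0.51 and -0.57 (SE 0.16). Against cold 0 h neither was called lower later: rplE had 0.93 at 3 h and -0.12 and -0.07 later, and rpsS 1.18 and then 0.06 and 0.09. At 24 h rpmA (tsl0166) was at -0.51 after 0.58 at 3 h (SE 0.13), and deoC (tlr1079), a deoxyribose phosphate aldolase gene, at -1.09 after 1.12 (SE 0.41). The control itself rose from 3 to 24 h in rpmA by 0.78 (SE 0.13) and in deoC from 13 ± 7.94 to 35.2 ± 12.1 per Mb, and against cold 0 h neither was called in opposite directions (rpmA -0.31 and -0.62, deoC 0.36 and -0.34, of which only rpmA at 24 h was called). In the other direction, tlr0319 was at 0.57 after -0.62 (SE 0.14) and tlr1926 at 1.13 after -0.39 (SE 0.14). Here the control fell, with changes of -1.01 and -0.98 (SE 0.14), and neither gene was called at 24 h against cold 0 h (-0.13 and -0.05).

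Libraries of each pair of groups were also exchanged between the groups. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each comparison 1 split, the real one, had as many called genes. The real value and the highest other were 1162 and 0 in heat 0.5 h vs heat 0 h, 1133 and 1 in heat 3 h vs control 3 h, 811 and 1 in heat 10 h vs control 10 h, and 246 and 6 in heat 24 h vs control 24 h. They were 795 and 0 in cold 0.5 h vs cold 0 h, 801 and 3 in cold 3 h vs control 3 h, 469 and 0 in cold 10 h vs control 10 h, and 942 and 4 in cold 24 h vs control 24 h. They were 143 and 0 in heat 0 h vs cold 0 h, and 5 and 1 in control 10 h vs control 3 h, and in control 24 h vs control 3 h the highest other was 49. Between the arms they were 1330 and 5 at 3 h, 1179 and 0 at 10 h, and 1170 and 0 at 24 h.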

How the results depend on the processing

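The tests with limma-voom, with the 3 and 10 h or only the 10 h controls, and of lists against 0 h were chosen after the results were seen. Of 231 counts under alternatives 190 stayed within 1.5 times the main value. Of 5375 values of named genes under alternatives 5024 kept their call, 344 lost it and 7 turned direction. Of these values 2232 came from leaving out 1 library. With 0 h as comparator 306 of 360 kept their call, 49 lost it and 5 turned. Against the 3 and 10 h controls 66 of 80 kept it, 12 lost it and 2 turned. The planned DESeq2 alternative was not run, as it needs read counts. With a log2 fold change of at least 1, the genes called were 401, 380, 205 and 33 at 0.5, 3, 10 and 24 h of heat and 153, 155, 76 and 248 in cold. They were 13 in heat 0 h vs cold 0 h, 1 in control 10 h vs control 3 h and 97 in control 24 h vs control 3 h. They were 708 for the difference of the 0.5 h responses and 529, 391 and 440 in heat 3 h vs cold 3 h, heat 10 h vs cold 10 h and heat 24 h vs cold 24 h. In heat 24 h vs control 24 h, 97 genes were called with only the libraries compared, 819 against 0 h, 1111 against the 3 and 10 h controls, 857 against the 10 h control, and 110 to 248 when 1 library was left out. In cold 24 h vs control 24 h it was 480 against the 10 h control, in place of 942. In heat 0 h vs cold 0 h the count was 94 with only the libraries compared and 20 to 95 with 1 left out. In control 24 h vs control 3 h it was 220 with only the libraries compared and 325 to 534 with 1 left out. In control 10 h vs control 3 h it was 2 with a pseudocount of 0.1, 1 with RLE factors, 0 with library totals alone, 2 with no filter, 0 with only the libraries compared, 4 with the replicate block, 18 with the block within arm, 1 with limma-voom, and 0 to 21 with 1 library left out. Genes called up and down at all 4 times were 31 and 128 in heat, 47 and 96 with library totals alone and 173 and 239 with 0 h as comparator; in cold they were 62 and 79, 125 and 47, and 124 and 118. Gene list tests gave 10 calls with an estimated correlation, against 25, and 21 to 26 with 1 library left out. Correlations of heat and cold with 0 h as comparator were -0.116, -0.0902 and -0.0944 at 3, 10 and 24 h, against 0.113, -0.00681 and -0.155. Against 0 h, cold values turned direction for serS tlr1552 at 3 h (-0.402), rpsS tsr0085 at 10 h (0.057) and 24 h (0.087), apcB tll0956 at 24 h (-0.10) and atpD tlr0525 at 24 h (-0.227). Against the 3 and 10 h controls, clpS tll0211 (0.091) and rlmD tlr0942 (0.31) turned at 24 h of cold.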

Other observations

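The genes and tests given here were chosen after their values were seen. Several genes without a symbol changed more than most named ones. tll1670 rose by 5.36 at 0.5 h of heat (SE 0.15) and by 2.16 at 3 h of cold. tll1985 had log2 fold changes of -5.27 and -4.64 at 0.5 and 3 h of heat and -1.98 at 3 h of cold (SE 0.135). tll0165 rose by 4.17 and 2.86 in heat at these times (SE 0.19) and by 1.75 at 3 h of cold. The neighbours of ntrB fell with it at 0.5 h of heat, with log2 fold changes of -4.30 for tlr1349 (SE 0.17), -4.01 for tlr1350 (SE 0.18) and -2.76 for tlr1352 (SE 0.18). Beside tlr0548 and tsr0549, tlr0547 was lower at all 4 cold times, with log2 fold changes of -0.83, -1.93, -1.96 and -1.93 (SE 0.13).

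The change of the control from 3 to 24 h had a Pearson r of 0.428 across genes with the response to 0.5 h of heat, and 303 of 341 genes called in both moved the same way. With the response to 0.5 h of cold r was -0.413, and 22 of 239 genes moved the same way. These comparisons share no libraries, and genes are not independent replicates.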
